A study of Homo sapiens with 6 samples.

How the data were processed

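RNA of parental 92.1 cells was measured in 6 libraries, 3 with a hairpin against BCAT1 and 3 with a negative-control hairpin, grouped by the genotype and title given in the labels. Per the labels' protocols, poly(A) RNA was fragmented, strands were marked with dUTP, and paired-end reads were sequenced on an Illumina instrument. The submitters' processing notes name fastp, HISAT2, StringTie and edgeR and the genome build GRCh38; their versions and roles and the gene annotation are not given in the sources used here. The values analysed are FPKM per gene and library, as deposited by the authors, with 31107 genes in the table and no read counts per library among the columns used. The ratio or fold column deposited by the authors equals the ratio of the group means of FPKM, to within a relative 3.8e-13 over the 25780 genes where both means are above 0. The deposited log2 column is the logarithm of that ratio. The deposited p-value and q-value columns are the authors' own; edgeR is among the tools in the submitters' notes, and the test and adjustment are not given in the sources used here. No per-sample value column was left unused (0).

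FPKM are not counts, so no count test was run here. The test used was limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with lmFit and eBayes with an intensity trend, a model of group alone, and Benjamini-Hochberg adjustment. A pseudocount of 1 was added, and genes entered with at least 1 FPKM in at least 3 libraries. This left 11644 genes, and BCAT1 was not among them, so it was also tested when added to these genes and without the filter. A fold change is thus on the log2(FPKM + 1) scale, which understates the change of low genes. Fold changes are shBCAT1 minus shNC, and every adjusted p of a gene is from limma unless a sentence says otherwise. Tables were read and drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

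Gene lists were tested with limma's camera at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 37 of 42 lists with at least 5 genes tested. The lists cover proliferation, metabolism, stress, signalling, immune response, lineage, RNA quality and markers of other cell types. Of 1169 entries, 1110 matched a gene symbol and 59 had no match. Camera was repeated with the correlation estimated per list, and fry was run beside it. GO and KEGG terms given in the table, of 10 to 500 tested genes, were tested per direction with one-sided Fisher exact tests against the tested genes with a term.

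The groups, the tests, the gene lists, the alternative settings and the rule for named genes were fixed before the data were examined. That rule names BCAT1 and BCAT2, then the 9 largest rises and falls past an adjusted p of 0.05 whose groups do not overlap and whose higher mean is at least 5 FPKM. It leaves out genes without a symbol, clone-style or noncoding names and names that end in P and digits. From each list that passed it names up to 4 members with the smallest adjusted p in the list's direction, and from other lists up to 2 members past the test. Only 3 genes that fell met the rule. Some genes that were tested are not reported here. The alternatives were another pseudocount (0.1), no filter, a stricter filter (a mean of at least 5 FPKM in a group), limma without the trend, median scaling, quantile normalization, the replicate number as a block, each library left out in turn, other thresholds and, for a fold of 1.2, limma's treat. DESeq2 and a comparison of counts with FPKM were planned for the case of counts and do not apply.

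The annotation used for coordinates, overlaps, transcript length and GC content was GENCODE release 29 on GRCh38, which holds 92.8% of the table's gene identifiers; the authors' annotation may differ. A gene's length and GC content are medians over its transcripts. Coordinates count from 1.

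Depth per library is unknown from FPKM. Low values fall on steps that reflect whole fragments, and the ratio of steps between libraries put their relative depths between 0.951 and 1.032, so depth differed little between groups. The libraries' FPKM summed to between 234945 and 245142. No pair of libraries shared more than 6 identical values above 0, so each was counted as a separate replicate. The labels do not say that the numbered samples of a group were separate cultures, nor whether the numbers stand for replicates or for different hairpins, so p-values measure only the spread between these samples, which may be technical. An exact 0 can be a failed estimate: 10 genes were listed at 0 in at least 1 library and at 5 FPKM or more in another, among them TEKTIP1, at 0 in shBCAT1 replicate 2 and between 17.2 and 21.6 FPKM in the others. Libraries were prepared with strand marking, but whether quantification used strand is not given in the sources used here, so overlapping and antisense genes are uncertain.

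The steps were tested on simulated data with the means and spreads of the 11644 genes. In 10 simulations of shBCAT1 against shNC with 200 genes changed each, limma called 82.8% of genes changed 1.5-fold, 96.1% of those changed 2-fold and 98.9% of those changed 3-fold on the log2(FPKM + 1) scale, and 5% of calls were unchanged genes. Among simulated lists of genes that vary independently, camera called 1 of 700 unmoved lists, and it called a list moved by 0.2 in 20 of 20 simulations. A planted term ranked first in the term test. Simulated genes varied independently with 1 spread per gene for both groups, while the real spread was wider between shBCAT1 libraries. The gene simulations also planted 200 changed genes, where the real comparison called 26. The simulated shares are thus not rates for the real comparison.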

Results

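The data were poly(A) RNA-seq profiles of parental cells of 92.1, an established human uveal melanoma cell line, after lentiviral delivery of a short hairpin RNA. Of the 6 libraries, 3 carried a hairpin against BCAT1 (shBCAT1) and 3 carried the negative-control hairpin (shNC). BCAT1 is the cytosolic branched-chain aminotransferase, which moves the amino group of leucine, isoleucine and valine onto 2-oxoglutarate. The question addressed was how the transcriptome of these cells differed when BCAT1 was knocked down. The table gave FPKM (fragments mapped to a gene, scaled by transcript length and by the fragments mapped in the library) for 31107 genes, and between 11527 and 11633 genes reached 1 FPKM in a library. Total depth is unknown from FPKM, but the steps between low values put the libraries' relative depths between 0.951 (shBCAT1 replicate 3) and 1.032 (shBCAT1 replicate 1) of that of shNC replicate 1. Mitochondrially encoded transcripts made up 12.57% of the FPKM in shBCAT1 replicate 3 and between 14.25% and 15.75% in each of the other libraries.

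BCAT1 was lower in all 3 shBCAT1 libraries than in all 3 shNC libraries. Its level was 0.379 ± 0.0521 FPKM with shBCAT1 and 0.974 ± 0.143 FPKM with shNC (mean ± SD, n = 3 each), so that 38.9% of the control level remained. The shBCAT1 libraries read 0.375, 0.433 and 0.329 FPKM, and the shNC libraries 0.820, 1.102 and 0.999 FPKM. The gene (ENSG00000060982; GRCh38 chromosome 12, 24810022 to 24949459, minus strand, protein-coding) was thus a low transcript even in the control cells. It reached 1 FPKM in too few libraries for the main test, and its difference of -0.52 on the log2(FPKM + 1) scale understates the change of so low a gene. Added to the genes tested it had an adjusted p of 0.0669 (limma), and with no filter on low values 0.251. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. In the authors' deposited table BCAT1 had a fold change of 0.389 and a q-value of 1.6e-13.

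BCAT2, the mitochondrial aminotransferase for the same amino acids, stood at 4.10 ± 1.48 FPKM with shBCAT1 and 4.57 ± 0.197 FPKM with shNC (n = 3 each; log2 fold change -0.17, SE 0.20, limma adjusted p = 0.859). The wide spread came from shBCAT1 replicate 2, at 2.40 FPKM, and without that library the BCAT2 difference was 0.10. The list of branched-chain amino acid catabolism genes, 24 of them tested, had a mean log2 fold change of 0.01 and did not pass the set test (camera adjusted p = 0.605). None of its genes passed over all genes tested or adjusted over the list alone (0 and 0), and the groups were apart for 1 of its 24 genes.

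**Figure D1:**
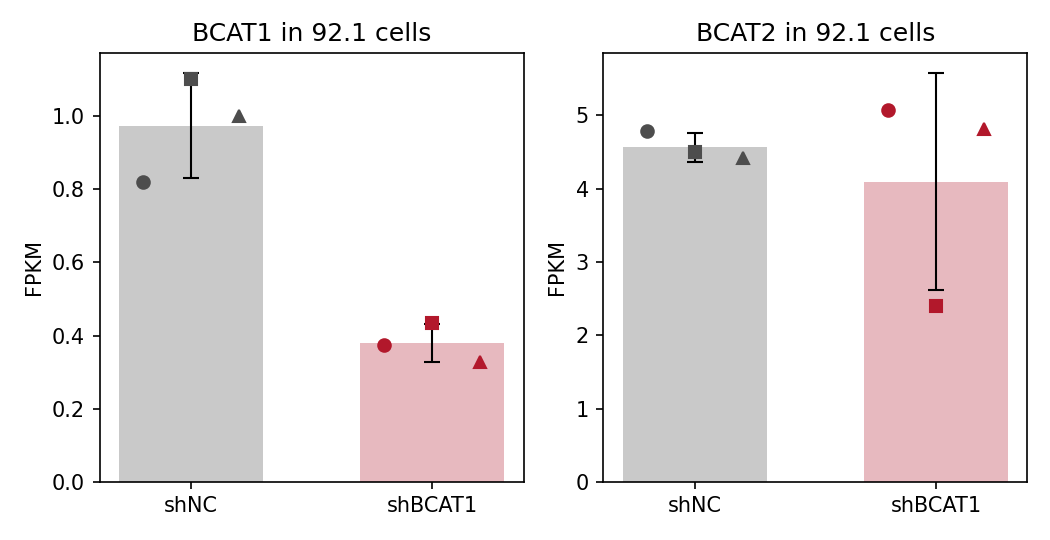
FPKM of BCAT1 and of BCAT2 in shNC and shBCAT1 libraries of 92.1 cells. Bars are group means, error bars are SDs over 3 libraries, and circles, squares and triangles are replicates 1, 2 and 3. The shBCAT1 libraries sit between 0.329 and 0.433 FPKM for BCAT1 and the shNC libraries between 0.820 and 1.102 FPKM, while for BCAT2 the groups overlap.

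Few genes separated the groups beyond the spread between libraries. That spread was unequal: the scaled median absolute log2 deviation was 0.141 to 0.181 between shBCAT1 libraries and 0.086 to 0.101 between shNC libraries. The first principal component (30.1%) set shBCAT1 replicate 1 (-11.29) against shBCAT1 replicate 2 (14.30), and the groups were apart on the second (27.1%). The limma model takes 1 spread per gene for both groups. Of 11644 genes tested, 26 passed an adjusted p of 0.05 (limma), 22 higher and 4 lower with shBCAT1. TPM4, a tropomyosin of actin filaments, rose from 18.6 ± 0.316 to 36.1 ± 2.77 FPKM (n = 3 each; log2 fold change 0.92, SE 0.06, adjusted p = 0.00446; chromosome 19, 16067021 to 16103005). MESD, a chaperone of lipoprotein receptors of the WNT pathway, rose from 7.38 ± 0.0955 to 11.1 ± 0.208 FPKM (log2 fold change 0.53, SE 0.05, adjusted p = 0.00953). GAS1, a membrane protein named for its expression in growth arrest, rose from 14.7 ± 0.945 to 23.0 ± 1.05 FPKM (log2 fold change 0.61, SE 0.06, adjusted p = 0.0216). PERP, a p53 target of cell junctions, rose by 0.61 ± 0.08 (log2 fold change ± SE, adjusted p = 0.0451) to 10.6 ± 1.09 FPKM. STX12, a syntaxin of endosomes, rose by 0.58 ± 0.08 (adjusted p = 0.0484) to 9.04 ± 0.936 FPKM. The call of STX12 was close to the threshold and was missed under 10 of 15 alternative settings (limma adjusted p from 0.0305 to 0.254). ANXA1, a phospholipid-binding annexin, rose from 14.3 ± 0.415 to 20.2 ± 1.03 FPKM, and HSDL2, a peroxisomal dehydrogenase-like protein, from 13.8 ± 0.697 to 19.4 ± 0.270 FPKM (adjusted p = 0.0291 and 0.0282).

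The 4 genes that fell were GPATCH4, HOXD1, DICER1 and ENSG00000173867, a gene listed by its identifier alone. GPATCH4, a G-patch domain protein, fell from 12.8 ± 2.01 to 4.92 ± 0.737 FPKM (n = 3 each; log2 fold change -1.22, SE 0.13, limma adjusted p = 0.0216; chromosome 1, 156594487 to 156601496). DICER1, the endonuclease that cuts microRNA precursors, fell from 5.05 ± 0.143 to 3.27 ± 0.114 FPKM (log2 fold change -0.50, SE 0.05, adjusted p = 0.0216; chromosome 14, 95086228 to 95158010). HOXD1, a homeobox transcription factor, fell from 25.6 ± 0.854 to 16.6 ± 1.98 FPKM (log2 fold change -0.60, SE 0.08, adjusted p = 0.0451). HOXD1 overlaps exons of HAGLR on the opposite strand. ENSG00000173867 fell from 1.27 ± 0.0762 to 0.480 ± 0.0609 FPKM, and its exons overlap those of DET1 and MRPL46 on the same strand. It was chosen after its values were seen, as were RPL17-C18orf32 and MIR34AHG.

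Only 3 of the 26 genes also passed a 2-fold change: GPATCH4 and the read-through genes RPS10-NUDT3 and RPL17-C18orf32, each of which joins a ribosomal protein gene to its neighbour. RPS10-NUDT3 rose from 10.79, 9.66 and 12.54 FPKM in the shNC libraries to 42.5 ± 8.83 FPKM with shBCAT1 (mean ± SD, n = 3; log2 fold change 1.85, SE 0.15, limma adjusted p = 0.00886; chromosome 6, 34284887 to 34426071). RPL17-C18orf32 was listed at 0 in all 3 shNC libraries and at 4.45, 2.89 and 2.25 FPKM with shBCAT1 (adjusted p = 0.00886; chromosome 18, 49481681 to 49492479). Both share exons with their parent genes, so their levels depend on how fragments were divided between gene models. RPS10 itself stood at 258 ± 33.4 FPKM with shBCAT1 and 313 ± 25.5 FPKM with shNC, and NUDT3 at 16.5 ± 1.58 and 19.1 ± 0.177 FPKM; neither passed the test (adjusted p = 0.481 and 0.429). MESD and the noncoding gene MIR34AHG passed with no filter on low values and the pseudocount of 1.

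Which genes passed the threshold changed with the library left out. Their number was 9 without shBCAT1 replicate 1, 20 without shBCAT1 replicate 2, 12 without shBCAT1 replicate 3, 1 without shNC replicate 1, 1 without shNC replicate 2 and 7 without shNC replicate 3, and of these 6, 11, 7, 1, 1 and 5 in turn were among the 26. The count of genes also past 2-fold was 0 without shNC replicate 1 and 0 without shNC replicate 2 (limma; 9 and 12 at an unadjusted p under 0.05). A fit with fewer libraries also has less power, so these counts do not separate the weight of a single library from that loss. With a lower threshold of evidence, 1074 genes had an unadjusted p under 0.05 (limma), 687 higher and 387 lower with shBCAT1. The groups did not overlap for 15.8% of the genes tested, where chance alone gives 10%. The authors' deposited table marked 350 genes as significant, 177 higher and 173 lower, which were those with p under 0.05 and a log2 fold change of at least 1 in size. Of these genes of the authors' deposited table, 301 reached 1 FPKM in no library and 310 had a q-value of 0.05 or more. All 26 genes called here had a q-value under 0.05 and the same direction in the authors' deposited table, where 187 genes had such a q-value.

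**Figure D2:**
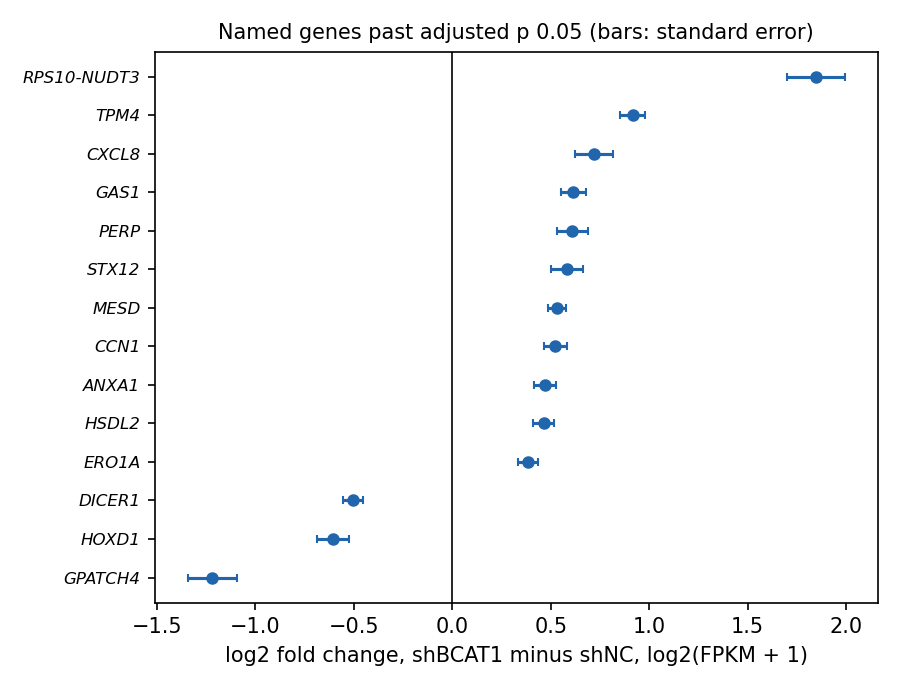
Log2 fold change of the genes named by the rule and past an adjusted p of 0.05, in shBCAT1 against shNC libraries (3 each), on the log2(FPKM + 1) scale; points are limma estimates and bars their standard errors. RPS10-NUDT3 lies farthest to the right at 1.85 and GPATCH4 farthest to the left at -1.22. Other genes past the threshold are not drawn.

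Gene groups were then compared with 42 lists, of which 37 had at least 5 genes tested. With camera's preset correlation between genes, 8 lists passed an adjusted p of 0.05, 4 higher and 4 lower. With an estimated correlation none of them did (0 of 37, also 0 at an unadjusted p under 0.05; lowest adjusted p = 0.671 with an estimated correlation). The shifts were small, below 0.15 on the log2 scale for each list mean.

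Genes of DNA replication and mitosis were slightly higher as groups with shBCAT1. The S phase and DNA replication list had a mean log2 fold change of 0.11 over 47 genes, 45 of them above 0 (camera adjusted p = 1.1e-09; adjusted p = 0.671 with an estimated correlation). None of its genes passed over all genes tested or adjusted over the list alone (0 and 0). CDC45, a part of the replicative helicase, stood at 24.5 ± 0.643 FPKM with shBCAT1 and 21.1 ± 1.01 FPKM with shNC (n = 3 each; limma adjusted p = 0.265). RRM2, a subunit of ribonucleotide reductase, stood at 19.9 ± 1.58 and 16.6 ± 0.680 FPKM (adjusted p = 0.294). E2F8, a repressor of the E2F family, and GINS4, of the replication fork, had log2 fold changes of 0.31 (SE 0.08) and 0.19 (SE 0.05). The G2/M and mitosis list had a mean of 0.07 over 45 genes, 40 of them above 0 (camera adjusted p = 6.5e-04; adjusted p = 0.671 with an estimated correlation), again with 0 genes past over all genes and 0 adjusted over the list alone. In it, MYBL2 stood at 96.5 ± 3.16 and 86.1 ± 1.56 FPKM and CCNB2 at 25.8 ± 0.556 and 23.4 ± 0.468 FPKM (adjusted p = 0.350 and 0.429). These members had the smallest adjusted p among those that rose. The 5 members below 0 included MKI67, at 12.03 FPKM with shBCAT1 and 12.08 FPKM with shNC, CDK1, at 29.61 and 29.62 FPKM, and CCNB1, at 69.8 and 72.7 FPKM.

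Genes of the pigment cell lineage were lower as a group. The melanocyte lineage and pigmentation list had a mean log2 fold change of -0.13 over 27 genes, 23 of them below 0 (camera adjusted p = 1.6e-07; adjusted p = 0.671 with an estimated correlation). For 12 of the 27 genes the shBCAT1 libraries all lay below the shNC libraries, but none passed over all genes or adjusted over the list alone (0 and 0). OCA2, a melanosomal transport protein, stood at 40.3 ± 1.15 FPKM with shBCAT1 and 46.2 ± 1.44 FPKM with shNC (n = 3 each; limma adjusted p = 0.256). EDNRB, the endothelin receptor of melanocytes, stood at 36.5 ± 6.11 and 46.8 ± 0.846 FPKM (adjusted p = 0.363), and MREG and MLPH, of melanosome transport, had log2 fold changes of -0.41 (SE 0.13) and -0.15 (SE 0.05). MREG passed over all genes without shBCAT1 replicate 2 (adjusted p = 0.0375). Without shBCAT1 replicate 1 the list's mean was -0.09, with a camera adjusted p of 3.0e-04. The members named above had the smallest adjusted p among those that fell. The 4 members above 0 included TYRP1, at 3300 FPKM with shBCAT1 and 3295 FPKM with shNC, and GPNMB, at 277.5 and 276.8 FPKM. PAX3 had a log2 fold change of 0.06 and PMEL one of -0.08.

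Lipid synthesis lists were lower too, by an amount that came mostly from 1 library. The cholesterol biosynthesis list had a mean log2 fold change of -0.10 over 22 genes, 17 of them below 0 (camera adjusted p = 0.00186; adjusted p = 0.727 with an estimated correlation). The fatty acid synthesis and desaturation list had a mean of -0.07 over 20 genes, 16 of them below 0 (camera adjusted p = 0.0164; adjusted p = 0.716 with an estimated correlation). Neither held a gene past the test over all genes or adjusted over the list alone (0 and 0 in each). SQLE, the squalene epoxidase, stood at 111 ± 10.4 FPKM with shBCAT1 and 128 ± 3.72 FPKM with shNC (n = 3 each; limma adjusted p = 0.475). SCD, the stearoyl-CoA desaturase, stood at 133 ± 18.1 and 153 ± 1.09 FPKM, and FASN at 57.5 ± 7.68 and 65.2 ± 4.50 FPKM (adjusted p = 0.552 and 0.663). Without shBCAT1 replicate 1 the cholesterol mean was -0.02 (camera adjusted p = 0.283) and the fatty acid mean -0.02 (0.285). The fatty acid list also missed the threshold without shNC replicate 2, at 0.0542.

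The list of immediate early genes and the list of NF-kappa-B targets and cytokines were higher as groups. The immediate early list had a mean log2 fold change of 0.13 over 18 genes, 14 of them above 0 (camera adjusted p = 0.00281; adjusted p = 0.671 with an estimated correlation). None of its genes passed over all genes, and 3 passed adjusted over the list alone: IER2 at 26.5 ± 2.53 FPKM with shBCAT1 and 20.2 ± 0.568 FPKM with shNC, KLF4 at 1.66 ± 0.182 and 1.09 ± 0.0719 FPKM, and NR4A2 at 2.46 ± 0.229 and 1.83 ± 0.128 FPKM (n = 3 each). With a stricter filter the list just missed the threshold (camera adjusted p = 0.0506). The NF-kappa-B targets and cytokines list had a mean of 0.14 and a median of 0.09 over 11 genes, 10 of them above 0 (camera adjusted p = 0.0164; adjusted p = 0.671 with an estimated correlation). In it CXCL8, a chemokine that attracts neutrophils, rose from 1.07 ± 0.0957 to 2.43 ± 0.419 FPKM (log2 fold change 0.72, SE 0.10, limma adjusted p = 0.0451), the only member past over all genes (1) or adjusted over the list alone (1). NFKBIA, the inhibitor that NF-kappa-B itself induces, stood at 12.6 ± 0.637 and 11.5 ± 0.178 FPKM (adjusted p = 0.594). Of the list's 26 entries only these 11 were tested. For the cytokine gene CCL2 the groups overlapped (log2 fold change 0.29, limma adjusted p = 0.645), and the cytokine gene CSF1 had a log2 fold change of 0.02. This list's call was lost without shBCAT1 replicate 1 (camera adjusted p = 0.0876), without shBCAT1 replicate 2 (0.0952) and without shNC replicate 3 (0.101), and with a stricter filter, which lowered the list mean to 0.04 (0.416).

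The nuclear oxidative phosphorylation list had a mean log2 fold change of -0.04 over 77 genes, 56 of them below 0 (camera adjusted p = 0.0430; adjusted p = 0.857 with an estimated correlation), and 0 genes passed over all genes or adjusted over the list alone. COX6A1, a subunit of cytochrome c oxidase, stood at 107 ± 9.09 FPKM with shBCAT1 and 122 ± 6.36 FPKM with shNC (n = 3 each; limma adjusted p = 0.494). The list mean came from shBCAT1 replicate 2, at -0.16 below the shNC mean, and without that library it turned to 0.02 (camera adjusted p = 0.288). The call was also lost without shNC replicate 1 (0.115), without shNC replicate 2 (0.148), with a pseudocount of 0.1 (0.0541) and with a stricter filter (0.0731). Without shBCAT1 replicate 1 the oxidative phosphorylation mean was -0.08. Cytosolic ribosomal protein genes were also lowest in shBCAT1 replicate 2, at -0.17 against the shNC mean, and highest in shBCAT1 replicate 1, at 0.15.

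**Figure D3:**
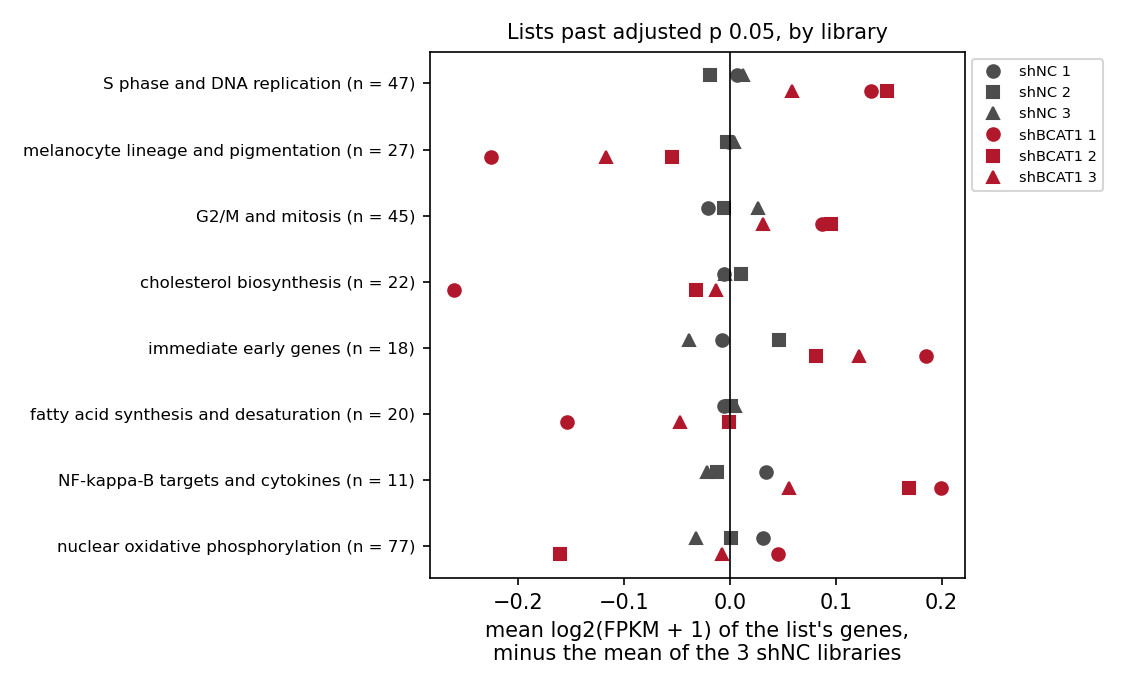
Mean log2(FPKM + 1) of the genes of each list past an adjusted p of 0.05, per library, with the mean of the 3 shNC libraries subtracted. Black symbols are shNC and red symbols shBCAT1 libraries, and shapes are replicate numbers; n is the number of genes tested. In the cholesterol biosynthesis list shBCAT1 replicate 1 stands apart at -0.26, and in the nuclear oxidative phosphorylation list shBCAT1 replicate 2 stands apart at -0.16.

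Among the 29 lists that did not pass, the YAP and TAZ targets had a mean log2 fold change of 0.08 over 17 genes (camera adjusted p = 0.0699). In this list CCN1, a secreted matricellular protein, rose from 5.03 ± 0.312 to 7.66 ± 0.342 FPKM (n = 3 each; log2 fold change 0.52, SE 0.06, limma adjusted p = 0.0282). CCN1 was the 1 member past over all genes, and adjusted over the list alone 2 passed, CCN1 and its relative CCN2 (5.26 ± 0.242 and 3.98 ± 0.262 FPKM). ERO1A, an oxidase that makes disulfide bonds in the endoplasmic reticulum, rose from 11.4 ± 0.308 to 15.2 ± 0.593 FPKM (log2 fold change 0.38, SE 0.05, adjusted p = 0.0451). It belonged to both the unfolded protein response list and the hypoxia list, was the 1 member of each past over all genes and the 1 adjusted over the list alone, and neither list passed (camera adjusted p = 0.190 and 0.696). Glycolysis genes had a mean of -0.05 over 20 genes (camera adjusted p = 0.0600), with 0 genes past on either count.

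Lists tied to amino acid use did not pass camera, which tests for a shift of a list in 1 direction. The mean log2 fold change was -0.02 for mTORC1 amino acid sensing (35 genes, camera adjusted p = 0.454), -0.04 for amino acid transport (14 genes, 0.291) and 0.01 for glutamate and glutamine metabolism (23 genes, 0.768). It was 0.02 for the ATF4 integrated stress response (30 genes, 0.605) and 0.02 for the chromatin and RNA dioxygenases that use 2-oxoglutarate (26 genes, 0.623). Fry's mixed test, which counts movement of members in either direction, gave unadjusted p = 8.9e-06 for the glutamate list. It gave 0.0103 for the dioxygenases, 0.0428 for the ATF4 list, 0.0651 for amino acid transport and 0.242 for mTORC1 sensing. Over all genes 0 members of these lists passed. Adjusted over the list alone, 2 passed in the glutamate list, CTPS1 (7.75 ± 0.411 FPKM with shBCAT1, 6.19 ± 0.119 FPKM with shNC) and ALDH4A1 (4.42 ± 0.0828 and 3.63 ± 0.192 FPKM), and 1 in the ATF4 list, DDIT4 (5.60 ± 0.270 and 4.22 ± 0.140 FPKM; n = 3 each), and 0 in the other lists of this group. Mean and median differed in sign for 7 of the 37 lists, among them amino acid transport, with a median of 0.00, and the type I interferon response, where camera's direction also differed from the mean; none of the 7 passed. The p53 targets (24 genes, mean 0.03, camera adjusted p = 0.392), the type I interferon response (19 genes, mean 0.00, 0.987) and the uveal melanoma prognostic panel (11 genes, mean 0.01, 0.938) held 0 genes past on either count.

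Markers of other cell types were mostly near 0, and none of those expressed passed the test over all genes. Of the retinal pigment epithelium markers SERPINF1 stood at 180 FPKM with shBCAT1 and 188 FPKM with shNC (limma adjusted p = 0.773), and RPE65 stayed under 0.01 FPKM in every library. FBLN1 among the fibroblast markers stood at 45.6 and 43.7 FPKM (adjusted p = 0.814), while COL1A2 stayed under 0.01 FPKM. The leukocyte marker PTPRC and the endothelial marker PECAM1 reached at most 0.00735 and 0.0162 FPKM. EMCN, another endothelial marker, stood at 14.3 ± 1.198 and 12.1 ± 0.676 FPKM (n = 3 each; adjusted p = 0.368), with no overlap between the groups, and the epithelial marker ESRP1 at 13.2 and 14.1 FPKM (adjusted p = 0.804). No GO or KEGG term was enriched among the genes that rose or fell (0 of 4302 tests past an adjusted p of 0.05 by one-sided Fisher exact tests, 62 at an unadjusted p under 0.05).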

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

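Robust variance shrinkage, the correction for GC content and length, camera with trended variance and the splits for the count of genes were chosen after seeing the data. BCAT1 stayed lower under each alternative that gave a value, from -0.57 to -0.47 over the left-out libraries, and was -1.16 with a pseudocount of 0.1, which by construction weighs low values more; limma's trend, robust shrinkage and the stricter filter give no other value for it. Its adjusted p when added to the genes tested lay between 0.0523 (GC and length correction) and 0.296 over the alternatives. The 26 genes past an adjusted p of 0.05 became 3 with no filter on low values, where 31107 genes were tested, 5 at an adjusted p under 0.01, 67 under 0.1, and between 1 and 20 with a library left out. With the replicate block 5 genes passed, all among the 26. Same-numbered libraries deviated together with correlations of only 0.08, -0.12 and -0.06, and not every library correlated best with its own number. These values gave no sign that the numbers pair the samples. With 3 libraries per group they cannot settle it, and the labels do not say, so pairing stays open. The 3 genes that also passed 2-fold became 6 with a pseudocount of 0.1, 0 with no filter (6 at an unadjusted p under 0.05 in limma), and between 0 and 4 with a library left out. The 8 lists became 0 with an estimated correlation and 0 with fry (0 and 6 at an unadjusted p under 0.05), between 6 and 13 with a library left out, and 9 with trended variance. Enriched terms stayed at 0 under each alternative. The main test offered only 18 genes that rose and 3 that fell to the GO terms, and 12 and 2 to the KEGG terms. Some alternatives called as few as 1 gene, so this 0 says little about stability. Signs turned for 3 results: nuclear oxidative phosphorylation, from -0.084 to 0.019 over the left-out libraries, BCAT2, from -0.32 to 0.095, and branched-chain amino acid catabolism, from -0.010 to 0.027, and at -0.012 with no filter; apart from the left-out libraries the cause was not tested. Over the named and called genes, 664 of 849 values under an alternative kept direction and side of the threshold, 183 missed the threshold and 1 newly passed. All 183 were of genes called in the main test. The 664 include named genes that had not passed and stayed above the threshold, so this share overstates how stable the calls were. For example, the threshold was missed under 3 of 15 alternatives for TPM4, 11 of 15 for ERO1A and 12 of 14 for ZNF138. Over the lists, 131 of 162 values kept direction and side of the threshold and 28 missed it. Depth limits low genes most, and BCAT1 is one of them.

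Other groupings of the 6 libraries bear on the counts. There are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 26 genes and the highest other 3, so 1 split reached the real count. For genes also past 2-fold the real count was 3 and the highest other 3 (2 splits). For lists the real count was 8 and the highest other 10, and 6 splits reached the real count. For terms both were 0, in all 10 splits. The other splits called between 0 and 3 genes, too few for a term to pass or fail in a telling way.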

Other observations

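The test on members varying together, the readings of the chromosome 19 test and of locus totals, and the KEGG and Reactome sets were chosen after the result was seen.

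Some genes too low for the main test differed strongly between the groups; those named here were chosen after their values were seen. SNX22, a sorting nexin (chromosome 15, 64151715 to 64157481), stood at 0.037, 0.027 and 0.031 FPKM with shBCAT1 and 0.910, 0.870 and 0.643 FPKM with shNC, so that 3.9% of the control level remained. MIR34AHG, the host transcript of the p53-induced microRNA miR-34a (chromosome 1, 9148011 to 9198906), stood at 0.459 ± 0.0404 FPKM with shBCAT1 and 0.0177 ± 0.00390 FPKM with shNC (n = 3 each), 25.9-fold higher by the ratio of means. With no filter the limma adjusted p was 0.0383 for MIR34AHG and 0.150 for SNX22. With no filter and a pseudocount of 0.1 it was 0.0532 for each, so MIR34AHG then missed the threshold. Exact two-sided permutation tests gave p = 0.1 for each, the smallest that 3 against 3 allow. In the authors' deposited table their q-values were 4.4e-44 and 4.8e-48. The p53 target list as a whole had a mean log2 fold change of 0.03 over 24 genes.

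Zinc finger genes formed a further group. Camera over 588 KEGG and Reactome terms called 12 at an adjusted p of 0.05, 10 higher and 2 lower with shBCAT1, and 0 with an estimated correlation. The Reactome group of KRAB zinc finger proteins that bind KAP1 led them, with a mean log2 fold change of 0.09 over 222 genes (adjusted p = 5.9e-09; adjusted p = 0.995 with an estimated correlation). The KEGG DNA replication term had a mean of 0.09 over 35 genes (adjusted p = 0.00104; adjusted p = 0.995 with an estimated correlation), and the KEGG glycolysis and gluconeogenesis term a mean of -0.07 over 40 genes (adjusted p = 0.0171; adjusted p = 0.995 with an estimated correlation).

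Of 359 tested genes with a ZNF symbol, 70.8% lay above 0, with a median log2 fold change of 0.06; ZNF267, ZNF616 and ZNF138 passed the test over all genes. Among 10000 random lists matched on mean expression the median reached at most 0.0248. GC content or length does not account for it as a whole, since after correction the median was 0.050, above the range that holds 95% of the matched lists, which ended at 0.008. A higher dose of chromosome 19 as a whole is argued against by a reading chosen after the result was seen. The other 659 genes of that chromosome had a median of -0.0014 (bootstrap 95% range -0.0079 to 0.0045). Its ZNF genes stood at 0.08 and those elsewhere at 0.03. The median elsewhere fell short of the share of the chromosome 19 median fixed beforehand for arguing against dose. By the criteria fixed beforehand the test thus decided neither way, since the other genes had not risen. A gain of the zinc finger clusters alone was not tested. A response of these genes to the hairpin may be a biological explanation and stays untested, and variation shared by the genes between libraries stays open (camera p = 0.0654 with an estimated correlation).

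The S phase and DNA replication list was higher in each shBCAT1 library than in each shNC library, at 0.13, 0.15 and 0.06 against the shNC mean. GC content and length as the whole cause are argued against by the corrected mean of 0.11 (camera adjusted p = 8.9e-10), and a single deciding library by the lowest mean of 0.10 over the 6 left-out libraries. Members varying together between libraries of a group stay open, because with a correlation of 0.18 estimated from the residuals the list's camera p was 0.0584. A change in the share of cycling cells with the knockdown may also account for it and was not tested.

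RPS10-NUDT3 may have risen because fragments were divided differently between overlapping gene models. The 37 tested read-through genes had a median within-group SD 3.2 times that of genes of the same level. When FPKM was weighted by transcript length in kilobases and summed over RPS10-NUDT3, RPS10 and NUDT3, the locus totalled 412 ± 25.0 with shBCAT1 and 415 ± 15.1 with shNC (n = 3 each, exact two-sided permutation p = 0.8), a ratio of 0.992. A shift between transcripts of the locus in the cells would leave the same total, and these values do not separate the explanations.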
